A study of Mus musculus with 6 samples.

How the data were processed

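Messenger RNA was measured by RNA sequencing in 6 mouse livers, 3 from Alkbh5-flox mice and 3 from Alkbh5-HKO mice. The sample titles write the second group as Alkbh5-CKO. Neither abbreviation is spelled out in the sources used here. The labels speak of 3 independent biological replicates per group. The series text gives an age of 9 weeks, whereas the labels' extract protocol gives 9 weeks of normal chow. Sex, feeding state at collection and time of day are not given in the sources used here.

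Per the labels' protocols, poly(A) RNA was selected with oligo-dT beads and sequenced in read pairs on an Illumina NovaSeq. Per the series text, the submitters aligned the pairs to the mouse genome GRCm38.p6 with HISAT2 2.0.5 and counted reads per gene with featureCounts 1.5.0-p3. The submitters' processing notes also name CASAVA and DESeq2 1.20.0. The annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Antisense or overlapping genes may therefore share reads, and near-identical paralogs may have gained or lost reads.

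The deposited values are FPKM, fragments per kilobase of gene length scaled by a library size, in 1 column per library for 41838 genes. Gene identifiers are NCBI Gene numbers, and 230 loci carry no gene name. The authors' FPKM keep the underlying counts. In each library 100% of the products of FPKM and the deposited gene length were whole multiples of 1 step, within a tolerance of 0.001, which gave the reads back. The library size that the authors divided by was 0.925 to 1.08 times the sum of those reads, for a reason not given in the sources used here. The recovered depth was 14907384 to 17034754 reads per library.

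All values below were computed from the deposited FPKM with R 4.3.3, limma 3.58.1 and statmod 1.5.0, and drawn with Python 3.11.15 and matplotlib 3.10.9. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 10453 in all. The test was limma with its trend and robust options on log2(FPKM + 1), Alkbh5-HKO minus Alkbh5-flox, with no covariate and Benjamini-Hochberg (BH) adjustment at 0.05. The added 1 shrinks the fold change of genes with low FPKM. Gene lists were tested with limma camera at a preset correlation of 0.01, where at least 5 members were tested, with BH adjustment over lists. Camera with an estimated correlation and limma fry were alternatives.

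Before the data were examined, 32 gene lists were fixed, 18 by function and 14 by cell type, with 503 symbols. Of these, 502 were found in the file, 3 of them under another symbol. The rule for named genes was fixed with them. It took Alkbh5, 9 genes of interest, the 12 protein-coding genes with the largest higher and the 12 with the largest lower fold change among those that passed and did not overlap between groups, and up to 3 passing members of each list. This named 36 genes. A further 36 were chosen after their values were seen, as examples of list members and of calls beyond the rule. A few other list members were examined and are not reported here.

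The tests were first run on simulated reads drawn from the means and depths of these libraries. Their dispersions were used after being pulled toward the median, and each gene was drawn independently. For Alkbh5-HKO minus Alkbh5-flox over 10324 genes, limma recovered 64 of 100 genes changed 2-fold and 90 of 100 changed 4-fold, and called 9 of 10113 unchanged genes. Camera called the list that had been changed, with an adjusted p of 1.3e-23, and 0 of 25 other lists. Simulated list members were not correlated, whereas camera estimated a correlation of 0.608 for the real cholesterol list and 0.203 for the interferon list. The simulation therefore does not show how often camera calls an unchanged list in these data.

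Alternatives covered the pseudocount (0.1 or 5), the filter (none, or a mean FPKM of at least 5), median-of-ratios and quantile scaling, TPM, eBayes without trend and robust, a minimum of 1.5-fold, the replicate number as a block, each library left out in turn, and voom on the recovered reads. Rescaling to the sum of the recovered reads, with limma or voom, was added after the data were seen. Libraries of a group were compared by a chi-square over genes with at least 10 reads in a pair. It gave 38.9 to 90.3 per degree of freedom, so no library was a copy of another.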

Results

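Liver transcripts were compared between 3 Alkbh5-flox mice, which carry the floxed gene, and 3 Alkbh5-HKO mice, in which Alkbh5 was targeted. The series set out to describe the effects of ALKBH5 on liver function. ALKBH5 removes the methyl group of N6-methyladenosine (m6A) from RNA. Recovered depth was 16956271, 15015208 and 15204835 reads in flox libraries 1 to 3 and 15649531, 17034754 and 14907384 in HKO libraries 1 to 3, and 18683 to 19525 genes had a value above 0. The 10 most abundant genes took 18.8% to 21.2% of the reads. Mitochondrially encoded genes took 3.66%, 4.22% and 4.38% in flox and 5.67%, 4.68% and 4.35% in HKO. The first principal component, with 44% of the variance, placed the flox libraries at -22.7, -22.5 and -13.7 and the HKO libraries at 38.6, 15.7 and 4.52. HKO library 1 thus lay apart from the rest of its group. The second, with 24.2%, placed flox at -17.5, -10.18 and 16.67 and HKO at -20.01, 20.95 and 10.07. It crossed the groups, with flox library 3 on the side of HKO libraries 2 and 3. Values below are FPKM as mean ± SD (n = 3), and fold changes are log2 of FPKM + 1, HKO minus flox.

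Alkbh5 (gene 268420, chromosome 11, 60537683 to 60558512, plus strand, GRCm38.p6) fell from 16.5 ± 1.56 in flox to 0.476 ± 0.0323 FPKM in HKO livers, which left 2.89% of the flox level. Its log2 fold change was -3.56 (SE 0.12), with an adjusted p of 8.14e-05 by limma with BH adjustment, and each HKO library lay below each flox library. The value covers the whole gene, and the deleted part is not given in the sources used here. Fto, the other known m6A demethylase, was at 7.38 ± 0.6 in flox and 7.77 ± 0.553 in HKO (log2 0.07, limma with BH adjustment, adjusted p = 0.8). Of the 16 tested genes of the m6A machinery, 5 were higher and 11 lower, and 0 passed either over all genes or adjusted over the list alone (median log2 -0.08, camera BH adjusted p = 0.424, and adjusted p = 0.792 with an estimated correlation). Among them, the methyltransferase subunits Mettl3 and Mettl14 had log2 values of -0.12 and -0.07, the m6A reader Ythdf2 -0.39 and the writer cofactor Zc3h13 -0.32. Alkbh5 passed in each of its 18 alternatives, which do not include the minimum of 1.5-fold.

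Across the 10453 tested genes, 28 rose and 23 fell in HKO livers (limma, BH adjustment at 0.05), with absolute log2 fold changes of at least 0.80 and a median of 1.36. All 51 were separated between the groups, and 45 were protein-coding and 4 long noncoding. Over all tested genes 25.4% were separated, where chance gives 10%. Among the protein-coding genes that passed, the largest increase was in the glutathione transferase Gsta1 (0.213 ± 0.368 to 12.3 ± 6.66, log2 3.39). Next among them were the interferon-induced Ifi44 (2.51), the cytochrome P450 Cyp2a22 (2.01), the guanylate-binding protein Gbp3 (1.90) and Gsta2 (1.6). Fam13a (1.58), Ifit3 (1.52) and the peroxisomal transporter Abcd2 (1.5) followed. The carboxylesterase Ces1b rose by 1.40. Beside Alkbh5, the largest decrease among protein-coding genes that passed was in the acyl-CoA thioesterase Acot1 (64.5 ± 17.2 to 9.31 ± 3.87, log2 -2.70). Next among them were the mitochondrial carrier Slc25a30 (-2.53), the cell cycle transcription factor E2f8 (-2.23) and Ces4a (-2.12). The lipid droplet proteins Plin5 (-2.03) and Plin4 (-1.87) and the globin Hbb-bt (-1.95) followed. After these came the acetylcholine receptor subunit Chrna2 (-1.50), the peroxisomal thiolase Acaa1b (-1.34), the adhesion protein Nectin2 (-1.33) and Hsdl2 (-1.26). Adjusted p-values of these named genes were 0.0167 to 0.0475 by limma with BH adjustment, apart from Alkbh5. Gsta1 and Gsta2, Cyp2a22, Ces1b, Acot1, Acaa1b, Ifit3 and the globins have near-identical relatives, so their values are uncertain where reads were shared. At an unadjusted p under 0.05, 896 genes were higher and 882 lower, where chance gives 523 in all. The series text states 1248 higher and 1107 lower genes, with a threshold not given in the sources used here. The counts depended on single libraries: limma passed 0 higher and 2 lower genes without flox library 1, 0 and 1 without flox library 2 or HKO library 2, 1 and 2 without HKO library 1, and 29 and 38 without flox library 3, with 1205, 1193, 1392, 1666 and 1876 genes at an unadjusted p under 0.05, and 1, 1, 1, 3 and 27 of the 51 calls remained. With no filter limma passed 0 higher and 1 lower (2514 at an unadjusted p under 0.05), a pseudocount of 0.1 gave 18 and 16, and voom on reads scaled to their own sum gave 78 and 42, of which 65% were higher against 54.9% here.

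**Figure D1:**
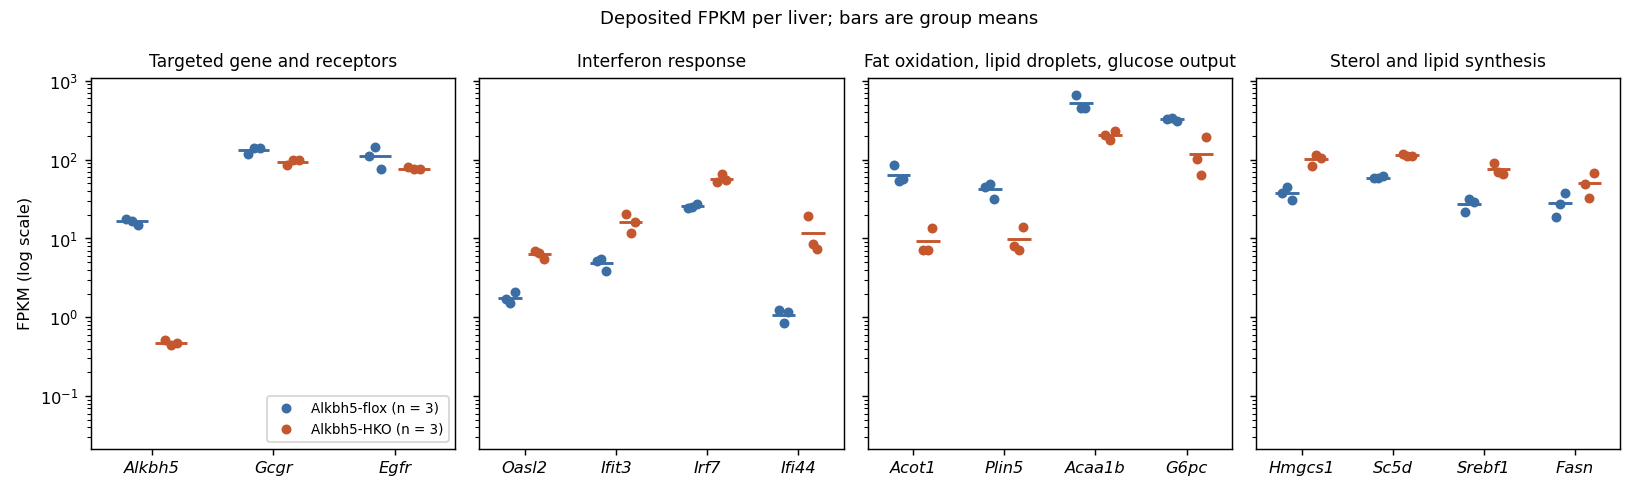
FPKM on a log axis for each flox (blue) and HKO (orange) liver, with bars at the group means, for the targeted gene and receptors, interferon response genes, fatty acid oxidation, lipid droplet and glucose output genes, and sterol and lipid synthesis genes. Alkbh5 lay at a mean of 16.5 in flox and 0.476 in HKO, and the groups of Egfr and Fasn overlapped.

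Interferon response genes were higher in HKO livers. All 23 tested members lay above flox on average, with a median log2 fold change of 0.96, and in 20 of them the groups did not overlap. Ifi44 rose from 1.08 ± 0.212 to 11.8 ± 6.59, Ifit3 from 4.86 ± 0.898 to 16.1 ± 4.2, Oasl2 from 1.78 ± 0.291 to 6.29 ± 0.706, Rtp4 from 7.78 ± 0.904 to 21.9 ± 4.42, and the transcription factor Irf7 from 25.5 ± 1.35 to 57.3 ± 7.35 (log2 1.13). These 5 passed over all genes, and 20 passed adjusted over the list alone. Usp18 (12.1 ± 1.37 and 35.7 ± 11.6) had an adjusted p of 0.0525 by limma with BH adjustment over all genes, and Rsad2 was at 2.56 ± 0.677 and 3.38 ± 1.30. Isg15, which has a near-identical relative and is uncertain where reads were shared, was listed at a mean of 0.0317 in flox and 0 in HKO and was not tested. The list had a camera BH adjusted p of 2.65e-19, an adjusted p of 0.298 with an estimated correlation, and an adjusted p of 0.0187 by fry, which asks whether members move one way on balance. With a pseudocount of 5 the median was 0.63.

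Genes of fatty acid oxidation and ketogenesis were lower in HKO livers. Of 21 tested members 19 were lower, with a median log2 fold change of -0.66, and 12 were separated. Acot1 passed over all genes, and 8 members passed as lower adjusted over the list alone. The latter included the fatty acid hydroxylase Cyp4a10 (329 ± 120 in flox, 123 ± 13.0 in HKO), the peroxisomal enzyme Ehhadh (135 ± 53.9 and 64.3 ± 9.89) and the hormone Fgf21 (4.10 ± 1.90 and 0.987 ± 0.761). Ppara, the receptor that drives many of these genes, was at 40.8 ± 12.9 and 30.8 ± 8.10 (log2 -0.37, limma BH adjusted p = 0.544). The camera BH adjusted p of the list was 1.91e-06, against an adjusted p of 0.433 with an estimated correlation, and 0.0608 by fry. Outside the list, Plin5 fell from 41.8 ± 9.18 to 9.72 ± 3.73 and Acaa1b from 523 ± 123 to 203 ± 26.5.

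Cholesterol synthesis and uptake genes were higher in HKO livers, in 21 of 22 tested members (median log2 0.62). Hmgcs1, an early enzyme of the pathway, rose from 37.9 ± 6.81 to 101 ± 16.8 (log2 1.40), and the late enzyme Sc5d from 59.2 ± 1.79 to 115 ± 3.93 (log2 0.94). These 2 passed over all genes and 7 adjusted over the list alone, Fdps (102 ± 25.5 and 196 ± 4.52) and Fdft1 (9.92 ± 3.34 and 22.3 ± 1.44) among the latter. Hsd17b7 was the 1 member below flox (log2 -0.28). The camera BH adjusted p was 6.46e-08, against an adjusted p of 0.792 with an estimated correlation, and 0.254 by fry. Without flox library 3 the median was 0.32, and the list still passed camera.

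Srebf1, which encodes a transcription factor of fatty acid synthesis, rose from 27.3 ± 5.27 to 75.5 ± 14.5 (log2 1.44, limma BH adjusted p = 0.041). It lies on chromosome 11 at 60199084 to 60222686, close to Alkbh5. Its targets Fasn (28.1 ± 9.77 and 50.2 ± 17.9, log2 0.81, limma BH adjusted p = 0.271) and Acly (31.7 ± 7.34 and 63.3 ± 20.8) did not pass. Of 23 tested genes of fatty acid and triglyceride synthesis, 9 were higher and 14 lower, with a median log2 of -0.18. Over all genes 1 passed, and adjusted over the list alone 1 passed as higher and 1 as lower (camera BH adjusted p = 0.687, and adjusted p = 0.922 with an estimated correlation). With any library left out Srebf1 did not pass (limma BH adjusted p of 0.0552 to 0.157).

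The glucagon receptor Gcgr was at 133 ± 12.5 in flox and 94.1 ± 8.14 in HKO (log2 -0.49, limma BH adjusted p = 0.159), with each HKO library below each flox library. The glucose-6-phosphatase gene G6pc was at 326 ± 11.5 and 119 ± 66.3 (log2 -1.59, limma BH adjusted p = 0.0997), likewise separated. Pck1, the other main enzyme of glucose output, was at 1650 ± 602 and 1087 ± 218 (log2 -0.55, limma BH adjusted p = 0.414), and Tat at 1355 ± 773 and 603 ± 189. Of 20 tested genes of glucagon signalling and gluconeogenesis 16 were lower (median log2 -0.16), and 0 passed by limma over all genes or adjusted over the list alone. The camera BH adjusted p was 0.083, against an adjusted p of 0.903 with an estimated correlation. The list passed camera without flox library 3 (BH adjusted p = 0.00535), without HKO library 3 (0.0481) and with no filter (0.0301), and over all alternatives its adjusted p was 0.00535 to 0.275. G6pc passed limma only without HKO library 3 (log2 -2.01, BH adjusted p = 0.0386, within 0.0386 to 0.284 over its alternatives).

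Egfr was at 111 ± 33.9 in flox and 77.2 ± 2.58 in HKO (log2 -0.47, limma BH adjusted p = 0.344), and the groups overlapped. Of 20 tested genes of EGFR, insulin and mTORC1 signalling 7 were higher and 13 lower (median log2 -0.10). None passed by limma over all genes or adjusted over the list alone, and the camera BH adjusted p was 0.574, against an adjusted p of 0.908 with an estimated correlation.

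Drug metabolism genes leaned higher in HKO livers, 16 of 23 tested members against 7 lower (median log2 0.41). Gsta1 and Gsta2 (5.32 ± 0.436 to 18.3 ± 3.01) rose over all genes, and adjusted over the list alone 7 passed as higher and 2 as lower. Cyp2a5 (342 ± 145 and 776 ± 75.0) and the retinaldehyde dehydrogenase Aldh1a1 (309 ± 61.6 and 585 ± 86.4) were among the higher, and Cyp2d9 (1323 ± 260 and 785 ± 141) and the xenobiotic receptor Nr1i2 (46.6 ± 13.2 and 27.6 ± 3.84) were the lower. The camera BH adjusted p was 0.0303, against an adjusted p of 0.792 with an estimated correlation, and 0.222 by fry. With a library left out the median was 0.222 to 0.537. The list passed in 10 of 18 alternatives, at a BH adjusted p of 0.000734 to 0.238 over all of them, and lost its call without flox library 3 (0.238) and without HKO library 1 (0.109). It also lost it with a mean FPKM of at least 5 (0.0832), with quantile scaling (0.0568), TPM (0.0556) and voom (0.0527), and on the sum of reads with limma (0.0844) or voom (0.126).

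Red cell transcripts were lower in HKO livers, in 6 of 6 tested members of the erythroid list (median log2 -1.77). The beta globin Hbb-bt fell from 31.7 ± 9.35 to 7.46 ± 2.34 (log2 -1.95, limma BH adjusted p = 0.0373). Hba-a1 was at 158 ± 67.7 and 40.8 ± 22.4, Hbb-bs at 205 ± 106 and 58.6 ± 22.8, and Alas2, of heme synthesis, at 50.5 ± 7.04 and 30.8 ± 4.81. Over all genes 1 passed, and adjusted over the list alone 5 passed, as lower. The camera BH adjusted p was 8.84e-05, against an adjusted p of 0.433 with an estimated correlation, and 0.0542 by fry. With no filter, which adds members near 0, the median was -0.70.

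Of the cell types other than red cells with enough tested markers, none passed camera. The median log2 was -0.11 for hepatocyte, 0.13 for periportal, -0.08 for pericentral, -0.16 for Kupffer cell, -0.03 for recruited monocyte, 0.06 for sinusoidal endothelium and 0.22 for stellate cell markers, with camera BH adjusted p-values of 0.424 to 0.909, and the pericentral and recruited monocyte medians changed sign under TPM. None of their members passed limma over all genes, and adjusted over the list alone 1 pericentral and 2 recruited monocyte markers did. The Kupffer list passed camera without flox library 2 (BH adjusted p = 0.0494) and without HKO library 2 (0.0447), within 0.0447 to 0.973 over its alternatives. Cholangiocyte, neutrophil, T and NK cell, B and plasma cell, adipocyte and pancreatic acinar markers had 2 or 3 tested members each, too few for the test. Of these, 2 T and NK cell markers were higher and 1 cholangiocyte marker lower by limma adjusted over the list alone, and with no filter the T and NK cell list (12 members, median log2 0.125) passed camera as higher (BH adjusted p = 0.00523). The core clock repressor Nfil3 fell from 5.16 ± 0.762 to 1.91 ± 0.0864 (log2 -1.08, limma BH adjusted p = 0.0372), the 1 member of 14 tested circadian clock genes to pass by either adjustment (list median log2 0.29, camera BH adjusted p = 0.48). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 45.1 ± 13.9 and 59.4 ± 28.1 (log2 0.30, limma BH adjusted p = 0.742), and of its list of 17 tested members 0 passed over all genes and 1, as lower, adjusted over the list alone. Camera BH adjusted p-values were 0.574 for the bile acid, cell cycle, mitochondrial respiratory chain and fibrosis lists and 0.424 for p53 targets, with median log2 values of 0.02, 0.14, 0.03, 0.09 and -0.27. The median and the mean had opposite signs for the bile acid (mean -0.13), mitochondrial (-0.03), pericentral (0.14), recruited monocyte (0.08) and acute phase (0.002) lists. Camera's direction was the sign of the mean for bile acid and pericentral, and that of the median for the other 3.

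**Figure D2:**
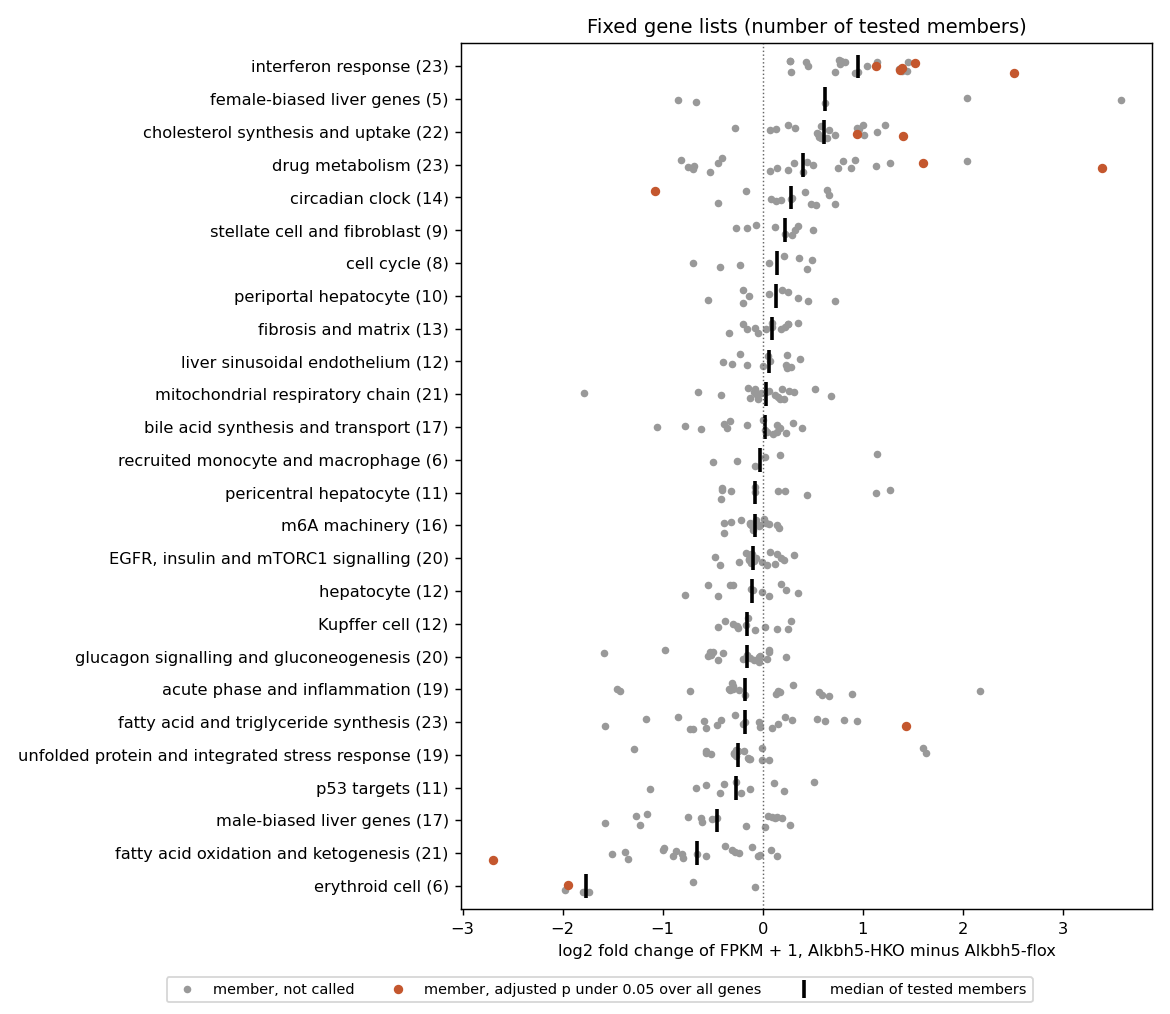
Log2 fold change of FPKM + 1, HKO minus flox, of each tested member (points) of the 26 tested lists, with the median as a bar and members that passed limma over all genes in orange. The interferon list has its median at 0.96 and the erythroid list at -1.77, and most of the other lists lie near 0.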

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

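The 2 settings on the sum of recovered reads were chosen after the data were seen. Alkbh5 passed limma in each of its 18 alternatives (log2 -5.10 to -1.97, BH adjusted p of 3.12e-05 to 0.00249, and -3.63 to -3.50 with a library left out). All 51 calls kept their direction in every setting that tested them. The main counts were 28 higher and 23 lower genes and 5 lists. With a library left out, higher genes ranged from 0 to 29, lower genes from 1 to 38 and called lists from 5 to 7, and 1, 1, 27, 3, 1 and 27 of the 51 calls remained without flox 1, 2 and 3 and HKO 1, 2 and 3. Those fits have fewer samples. A pseudocount of 0.1 gave 18 higher genes. With no filter 23371 genes were tested, and 0 higher and 1 lower gene and 8 lists passed, with 2514 genes at an unadjusted p under 0.05. Voom on the sum of reads gave 78 higher and 42 lower, and 49 of the 51 calls remained. Camera with an estimated correlation called 0 lists and fry 1. The replicate block gave 1 higher and 8 lower genes, 6 of them among the 51, and 6 lists. Libraries with the same number did not deviate together (correlations 0.153, -0.145 and -0.0514), and not every library correlated best with its own number, so the samples share only a number. Of the named genes' other values, 1035 kept their side of the threshold, 210 lost the call, 14 gained it and 1 changed sign: Mettl14, at -0.118 to 0.0297 with a library left out. The interferon, cholesterol, fatty acid oxidation and erythroid lists passed camera in all 18 alternatives. Of list medians 417 kept direction and call, 8 lost the call, 13 gained it and 24 changed sign, in lists near 0, for which the cause was not tested. With no filter, acute phase was at 0.017, cell cycle at -0.007, pericentral at 0.000 and recruited monocyte at 0.038. TPM gave 0.077 for pericentral and 0.044 for recruited monocyte. Recruited monocyte was at 0.008 with quantile scaling, and 0.039 by limma and 0.059 by voom on the sum of reads. With a library left out the medians ranged from -0.135 to 0.023 for EGFR, -0.099 to 0.124 for bile acid, -0.190 to 0.199 for acute phase, -0.015 to 0.125 for mitochondrial, -0.163 to 0.133 for pericentral, -0.400 to 0.058 for Kupffer, -0.249 to 0.167 for recruited monocyte and -0.022 to 0.217 for sinusoidal endothelium. Depth was 14907384 to 17034754 reads, and how it limits genes at low FPKM was not tested. Genes under a mean FPKM of 1 were left out of the main fit.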

Other observations

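The tests of the fixed lists and the gene and list counts over splits of the libraries were planned. The tests of explanations, of genes near Alkbh5 and of single lists over splits were chosen after the results were seen.

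Neither list of sex-biased liver genes passed camera. Of 17 tested male-biased genes 10 were lower, and 0 passed limma over all genes or adjusted over the list alone (median log2 -0.46, camera BH adjusted p = 0.083, and adjusted p = 0.453 with an estimated correlation), among them Ugt2b38 (27.1 ± 7.90 in flox, 8.77 ± 4.11 in HKO) and the urinary protein Mup21 (65.0 ± 21.2 and 28.7 ± 13.6). The list passed camera in 7 of 18 alternatives, at an adjusted p of 0.0278 to 0.254 over all of them. Of 5 tested female-biased genes 3 were higher (median log2 0.62, camera BH adjusted p = 0.424, and adjusted p = 0.903 with an estimated correlation), with a median of 0.171 to 1.108 with a library left out. Cyp2a4 was at 5.33 ± 5.81 and 61.8 ± 41.4 (log2 3.58) and Cyp2b9 at 0.940 ± 1.48 and 6.21 ± 3.2 (log2 2.04), the 2 that passed limma adjusted over the list alone, against 0 over all genes. The Y-linked Ddx3y was at 13.1 ± 0.893 and 14.4 ± 4.73, and Xist at 0.00824 and 0.00699, the pattern of male livers in both groups. The male-biased list includes the Y-linked Ddx3y, Kdm5d, Eif2s3y and Uty, which mark the sex of the mouse, so its count, median and camera p cover these too.

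Among calls outside the rule for named genes, the fetal liver gene Afp rose from 0.748 ± 0.249 to 3.17 ± 0.208 (log2 1.26, limma BH adjusted p = 0.0345). The acetyl-CoA enzymes Acat2 (20.1 ± 1.54 to 42.3 ± 0.886) and Acss2 (37.6 ± 4.24 to 99.4 ± 21.9) rose by 1.04 and 1.36 on the log2 scale (limma BH adjusted p = 0.0345 and 0.0441). Of other glutathione transferases, Gstm3 was at 42.0 ± 21.6 and 86.0 ± 12.9 and Gstp1 at 98.9 ± 24.6 and 57.4 ± 20.9, neither past the threshold over all genes, whereas Gstm3 passed adjusted over the drug metabolism list alone. In the unfolded protein and integrated stress list 16 of 19 tested members were lower (median log2 -0.24, camera BH adjusted p = 0.424), whereas Trib3 was at 3.81 ± 1.6 and 14.7 ± 9.30 and Asns at 3.50 ± 3.93 and 9.92 ± 2.11. It passed camera without flox library 3 (BH adjusted p = 0.014). Acute phase genes went both ways (9 higher, 10 lower, camera BH adjusted p = 0.909). The iron hormone Hamp was at 41.3 ± 26.0 and 264 ± 233 and Saa1 at 152.8 ± 82.0 and 49.5 ± 16.5, neither past the threshold. Without flox library 3 Saa1 passed limma (log2 -2.03, BH adjusted p = 0.0497).

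The interferon list was higher in HKO livers at a median log2 of 0.955 (95% bootstrap interval 0.769 to 1.356). The intervals in this paragraph resample the genes of a list, not the livers, so they leave out the spread between mice. More cells of a type would raise its markers at least as much. The median was -0.156 for Kupffer cells (12 tested markers, interval -0.277 to 0.081) and -0.026 for recruited monocytes (6 markers, -0.381 to 0.654). With a library left out these medians were -0.400 to 0.058 and -0.249 to 0.167, against at least 0.878 for the interferon list. These ranges, rather than the intervals, argue against the 2 cell types, within 3 livers per group. More T and NK cells could contribute and stay open, since 3 of 3 tested markers were higher (median 0.477, 0.171 to 1.097), too few to decide. A single HKO library is not the source, since the lowest median without an HKO library was 0.878. Neutrophils and B cells, loss of Alkbh5 as the direct cause, housing, litter and infection were not tested.

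Fatty acid oxidation genes were lower and cholesterol synthesis genes higher. Over 6 scalings the smaller of the 2 medians was 0.587 in size. A scaling factor moves all genes of a library alike. It could not set the 2 lists apart in opposite directions, whatever these medians had been. Feeding state could contribute: fed-induced minus fasting-induced genes scored 0.565 higher in HKO (0.836 without flox library 3, 0.246 without flox library 1), but flox library 3 at -1.911 lay above HKO library 1 at -2.002, so it stays open. Time of day could also contribute: evening minus morning clock genes scored 0.857 higher in HKO (0.364 without flox library 3) and separated the groups. They no longer did so without Nr1d1, Cry1 or Nfil3, a requirement set after the score was seen. Without Nfil3 the mean score was 0.686 higher in HKO, at 2.788, 3.22 and 1.448 in flox libraries 1 to 3 and 3.246, 3.111 and 3.157 in HKO. Flox library 2 then lay within the HKO range, and flox library 3 lay far below all others. Feeding state and time of day cannot be told apart from an effect of the genotype, because collection is not described.

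Globin transcripts were lower in HKO livers, with Hbb-bs at 205 ± 106 and 58.6 ± 22.8 FPKM. Less blood in the HKO livers could contribute and stays open, since of 5 other members of the erythroid list found in the file, 2 had each HKO library below each flox library. These were Alas2 and the low Slc4a1 (11, 12 and 8 recovered reads in flox libraries 1 to 3 and 0 in each HKO library), whereas Tfrc overlapped between groups. Fewer red cells in the mice would give the same values and was not tested.

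For the gene count, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many as the real 51, and the highest of the others gave 2. For the list count, 6 of the 10 splits gave at least the real 5, and the highest of the others gave 11. With 10 splits the share is never under 0.1, so the gene count could not reach a share under 0.05. The list count was not held back by this, since mixed splits reached it as well. The number of lists that camera called therefore does not set the real grouping apart from mixed ones. For the interferon, fatty acid oxidation and erythroid lists, the smallest camera p in another split was 5.78e-07, 0.000679 and 0.00116, against 1.02e-20, 2.2e-07 and 1.36e-05 in the real one. For the cholesterol and drug metabolism lists another split gave 3.21e-12 and 9.37e-05, smaller than the real 4.97e-09 and 0.00583. Genes within 10 Mb of Alkbh5 passed an unadjusted p of 0.05 in 26 of 167 cases, an odds ratio of 0.898 (95% interval 0.565 to 1.38) against other genes, and the 1 called gene among them was Srebf1.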
